A study of Mus musculus with 5 samples.

How the data were processed

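The series holds 5 bulk RNA-seq samples of mouse small cell lung cancer, a lung tumour of neuroendocrine cells. The labels describe lung tumours taken at necropsy and flash-frozen, with the genotype RPP, whose letters they do not expand. The treatment label was vehicle for 2 tumours and LSN for 3, and the series names the treatment as an inhibitor of Aurora A kinase, an enzyme of the mitotic spindle. The dose and length of treatment are not given in the sources used here. The design text of the series speaks of primary tumour cells, whereas every sample label speaks of a lung tumour, and the samples were treated here as pieces of tumour tissue.

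Per the labels' protocols, total RNA was extracted with a spin-column kit and a DNase step, libraries were made with a kit that does not keep the strand, and paired ends were read on a NovaSeq instrument. Per the labels' protocols, the authors mapped reads to the mouse genome build mm10 with STAR and computed differential expression with DESeq2. The version of STAR, the program that counted reads per gene and the annotation are not given in the sources used here. The authors deposited read counts per gene, whole numbers that had not been normalized, for 54532 genes in all 5 tumours. Of these genes, 54495 had an Ensembl identifier of GENCODE M21, and 98.3% of those had the same start and end as in that annotation. Coordinates are given as in the deposited table. Without strand information, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads of near-identical genes such as the H2, Gbp, Ifit, Oas and globin families may be shared between members, so values of single members are uncertain.

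Total counts were 17804648 and 17439049 in vehicle replicates 1 and 2 and 17870505, 19766604 and 19516606 in LSN replicates 1, 2 and 3. A count of 3, taken as the floor, corresponded to between 0.152 and 0.172 CPM, the count scaled to library size, which covers counting error only. Mitochondrial genes took 0.94 to 1.75% of the counts, ribosomal RNA genes 0.05 to 0.25%, and the 10 most abundant genes 2.92 to 3.79%.

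Groups were taken from the treatment label. Tumour numbers differed between all samples, so that nothing paired a vehicle with an LSN tumour, and the labels give no batch. Nothing in the labels says that each tumour came from a separate animal, so p-values measure the spread between these samples. The comparison of LSN with vehicle was made with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with a robust fit, TMM scaling and the filterByExpr filter at a minimum count of 10 and a minimum total count of 15, which kept 17906 genes. P-values were adjusted by the Benjamini-Hochberg method at 0.05, with 3 residual degrees of freedom. CPM values are scaled by TMM. An exact permutation test of 2 tumours against 3 cannot give a p below 0.1.

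Before the data were examined, 16 functional gene lists and 13 marker lists of other cell types were fixed from general knowledge. The functional lists covered mitotic genes, replication genes, Aurora A partners with the MYC family, type I interferon response, interferon gamma response, MHC class I presentation, MHC class II presentation, nucleic acid sensing, NF-kB and inflammatory cytokines, immune checkpoints, neuroendocrine genes, non-neuroendocrine genes, p53 targets, immediate early and stress genes, hypoxia and glycolysis, and senescence. The marker lists covered T and NK cells, B and plasma cells, macrophages and monocytes, neutrophils, dendritic cells, normal lung epithelium, endothelium, fibroblasts with smooth muscle, mesothelium, red blood cells, cardiac and skeletal muscle, liver, and thymus with lymph node. Each list with at least 3 measured genes was tested with camera of limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over all 29 lists. The median log2 fold change of a list is that of the differences in mean log2 CPM of its members, whereas log2 fold changes of single genes, given with their standard error (SE), come from edgeR.

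The rule for named genes, also fixed beforehand, took up to 12 genes per direction past the adjusted threshold with a mean of at least 1 CPM and all LSN tumours on one side of both vehicle tumours, leaving out predicted genes and pseudogenes. Since 0 genes passed in edgeR, it took the 5 genes per direction with the smallest unadjusted p under the same conditions, the 2 members of each list with the smallest p, and a fixed set of genes of mitosis, interferon signalling, antigen presentation and tumour identity. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

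Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, total counts without TMM, no count filter, a filter of 1 CPM in 2 samples, a fit that was not robust, a prior count of 0.5, camera with an estimated correlation, fry, a covariate of immune and stromal markers, which left 2 residual degrees of freedom, and leaving out each tumour in turn. Without one vehicle tumour, the lone vehicle tumour was assumed to vary like the LSN tumours. Further settings, added after seeing the data, were DESeq2 with each tumour left out, a covariate of normal lung markers, and chromosome 11 left out. The immune and stromal covariate was the mean log2 CPM of the T and NK cell, B and plasma cell, macrophage, endothelial and fibroblast lists. The normal lung covariate was that of the normal lung list. A list that is part of a covariate cannot be tested with it.

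The tests were tried on 1 set of simulated counts with the means, library sizes and spread of these tumours. In it, 50 genes each were changed by 2, 4, 8 and 16-fold among 17906 genes. The spread was that estimated by edgeR and genes were drawn independently, so structure shared between genes was not simulated and the model was edgeR's own. For LSN against vehicle, edgeR recovered 0, 8, 20 and 64% of these genes, with 4 false calls. DESeq2 recovered 8, 50, 60 and 88%, with 129 false calls. With a simulated biological coefficient of variation of 0.1, edgeR recovered 92% of the 2-fold changes, whereas the observed common value was 0.59. Per chromosome, medians were taken over genes with a mean log2 CPM above 4. GC content and length came from the GENCODE M21 transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.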

Results

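Gene expression was measured by RNA-seq in 5 mouse small cell lung cancer tumours, 2 labelled vehicle and 3 labelled LSN, the name the labels give to an inhibitor of Aurora A kinase. Total counts lay between 17439049 and 19766604 per tumour, with a count above 0 for 23446 to 24604 genes. The tumours differed widely from one another within each group. Pearson correlations of log2 CPM across genes ranged from 0.835 to 0.934, and the closest pair was vehicle replicate 2 with LSN replicate 1. The 2 vehicle tumours correlated at 0.887. The first principal component held 47.7% of the variance and placed vehicle replicate 2 at 101.4 and LSN replicate 1 at 79.1, with vehicle replicate 1 at -19.6 and LSN replicates 2 and 3 at -104.6 and -56.3.

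The comparison of LSN with vehicle asked, after the title of the series, whether mitotic and interferon-regulated genes differ in tumours exposed to the inhibitor. Cd274, which encodes the checkpoint ligand PD-L1, was higher in all 3 LSN tumours, at 50.0 ± 5.30 CPM (SD, n = 3) against 27.1 ± 7.15 CPM (SD, n = 2). Lists of interferon-regulated and MHC class I genes had slightly higher medians in the LSN group, and most mitotic genes differed little. The mean of the normal lung epithelium markers and that of the endothelial markers were lower in every LSN tumour, with list medians of -2.46 and -1.57 on the log2 scale. Genes with the smallest p-values among those higher with LSN lay mostly on chromosome 11.

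By edgeR, 0 of 17906 genes passed an adjusted p of 0.05, the smallest adjusted p being 0.9996. At an unadjusted p under 0.05 there were 764 genes, 190 higher and 574 lower, where chance alone would give 895. limma-voom also called 0 genes, with 858 at an unadjusted p under 0.05. DESeq2, the tool named in the labels, called 100 genes of 18547, 14 higher and 86 lower, with 1218 at an unadjusted p under 0.05. Every LSN tumour was above both vehicle tumours for 1518 genes (8.5%) and below both for 1866 genes (10.4%), where chance gives 10% in each direction. The DESeq2 count was 36 without vehicle replicate 2, 44 without LSN replicate 3 and 483 without LSN replicate 1. The edgeR counts at an unadjusted p under 0.05 without these 3 tumours were 309, 345 and 963 genes lower, and without vehicle replicate 2 there were 98 genes higher.

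Mitotic genes were measured for all 44 members of the list, and 36 had a log2 fold change above 0. Their median was 0.17, which limma camera called higher with LSN (adjusted p = 0.0223; adjusted p = 0.755 with an estimated correlation). Cenpe, a kinetochore motor, had a log2 fold change of 0.65 ± 0.28 (SE), from 132 to 207 CPM, and Hmmr, a spindle-associated protein, one of 0.82, from 130 to 229 CPM. Plk1, a mitotic kinase, was also higher in every LSN tumour, at 119 against 97.0 CPM, so that 3 of the 44 genes separated the groups upward, where chance gives 10%. Aurka, the kinase targeted by the inhibitor, was at 108 ± 32.7 CPM (SD, n = 3) with LSN and 96.9 ± 8.59 CPM (SD, n = 2) with vehicle. Log2 fold changes were 0.19 for Aurkb, 0.54 for Cdc20, -0.01 for Ccnb1 and 0.01 for Mki67, the last 2 changing sign with RLE scaling or with total counts. By edgeR, 0 members passed over all genes, 0 adjusted over the list alone and 0 reached an unadjusted p under 0.05. The mean log2 CPM of the list was 7.81 in LSN replicate 3 and between 6.97 and 7.29 in the other tumours. Without LSN replicate 3 the median was -0.08 (limma camera, adjusted p = 0.613), and without vehicle replicate 1 it was 0.06 (adjusted p = 0.433). It was called higher at 0.28 without vehicle replicate 2 and 0.30 without LSN replicate 2, and with a covariate at 0.43 (immune and stromal markers) and 0.52 (normal lung markers).

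Replication genes had a median of 0.13 over 34 members (limma camera, adjusted p = 0.0598, and adjusted p = 0.622 with an estimated correlation). The median was 0.026 without vehicle replicate 1 and 0.042 without LSN replicate 3. Prim1, a primase subunit, was at 182 against 135 CPM and Tyms, thymidylate synthase, at 126 against 95.7 CPM, both higher in all 3 LSN tumours. The replication list was called without vehicle replicate 2, at a median of 0.21 (limma camera, adjusted p = 0.0084), with the immune and stromal covariate (0.21, adjusted p = 0.00544) and with chromosome 11 left out (0.12, adjusted p = 0.0484). The 12 Aurora A partners and MYC family genes had a median of 0.11 and a mean of -0.12 (limma camera, adjusted p = 0.969), with medians of -0.03 without vehicle replicate 1 and -0.07 without LSN replicate 3. Among them, Ajuba, an activator of Aurora A, was lower in every LSN tumour, at 2.50 against 8.49 CPM, and Myc was at 10.8 against 17.7 CPM. Neither list had a member past the adjusted threshold of edgeR over all genes or adjusted over the list alone, and 0 members reached an unadjusted p under 0.05.

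Type I interferon response genes were mostly higher with LSN on average, and 28 of the 37 members had a log2 fold change above 0. Irf7, a transcription factor of the interferon response, was at 36.9 ± 29.2 CPM (SD, n = 3) against 16.4 ± 7.40 CPM (SD, n = 2), and its highest value, 69.4 CPM, was in LSN replicate 2. Dtx3l, a ubiquitin ligase, had a log2 fold change of 0.93 ± 0.35 (SE) and Trim25, a ubiquitin ligase of RNA sensing, one of 0.81 ± 0.35 (SE), both higher in all 3 LSN tumours. Isg15 was at 12.4 against 9.68 CPM, with groups that overlapped. The median of the list was 0.27 (limma camera, adjusted p = 0.016; adjusted p = 0.75 with an estimated correlation), and 5 members separated the groups upward, where chance gives 10%. By edgeR, 0 members passed over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. The list mean was 5.27 log2 CPM in LSN replicate 2 and between 3.67 and 4.33 in the others. Without LSN replicate 2 the median was -0.11 (adjusted p = 0.627), and without vehicle replicate 1 it was 0.18 (limma camera, adjusted p = 0.39). The list was called higher without vehicle replicate 2 (0.47), LSN replicate 1 (0.45) or LSN replicate 3 (0.68). With the immune and stromal covariate it was not called (0.10; limma camera, adjusted p = 0.441), and with the normal lung covariate it was called lower (-0.72, adjusted p = 0.000544).

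Interferon gamma response genes had a median of 0.38 over 28 measured members of 30, of which 22 were above 0 (limma camera, adjusted p = 0.00969; adjusted p = 0.565 with an estimated correlation). Cd274 (chromosome 19, 29367455 to 29388095) had the smallest p of the list, with a log2 fold change of 0.88 ± 0.29 (SE), an unadjusted p of 0.0263 and an adjusted p of 0.9996 by edgeR. Psmb8, an immunoproteasome subunit, was at 78.2 against 40.9 CPM and Irf1, an interferon-induced transcription factor, at 59.5 against 44.6 CPM, each higher in all 3 LSN tumours. Cxcl10, a chemokine that attracts T cells, was at 6.83 against 5.65 CPM. In edgeR, 0 members passed over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. The median was 0.16 without vehicle replicate 1 (limma camera, adjusted p = 0.662) and 0.27 without LSN replicate 1 (adjusted p = 0.0806). It was still called without LSN replicate 2 (0.31, adjusted p = 0.00804 by limma camera) and without vehicle replicate 2 (0.62), but not with the normal lung covariate (0.29, adjusted p = 0.0601).

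MHC class I presentation genes were above 0 for 21 of 23 members, with a median of 0.37 (limma camera, adjusted p = 0.00124; adjusted p = 0.649 with an estimated correlation). Canx, the chaperone calnexin, was at 628 ± 19.6 CPM (SD, n = 3) against 442 ± 36.6 CPM (SD, n = 2), and Psme2, a proteasome activator subunit, at 85.3 against 57.4 CPM, both higher in all 3 LSN tumours. The class I molecules themselves overlapped between groups. B2m was at 543 ± 372 CPM (SD, n = 3) with LSN against 502 ± 189 CPM (SD, n = 2), and H2-K1 at 758 against 661 CPM, with the highest values, 971 and 1245 CPM, in LSN replicate 2. The peptide transporter gene Tap1 was at 65.9 against 41.8 CPM. In edgeR, 0 members passed over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. The list mean was 7.28 log2 CPM in LSN replicate 2 and 6.28 to 6.50 elsewhere, and without that tumour the median was 0.09 (limma camera, adjusted p = 0.427). With the immune and stromal covariate the list was not called (0.069; limma camera, adjusted p = 0.344), and with the normal lung covariate it was called lower (-0.67, adjusted p = 0.00813).

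**Figure D1:**
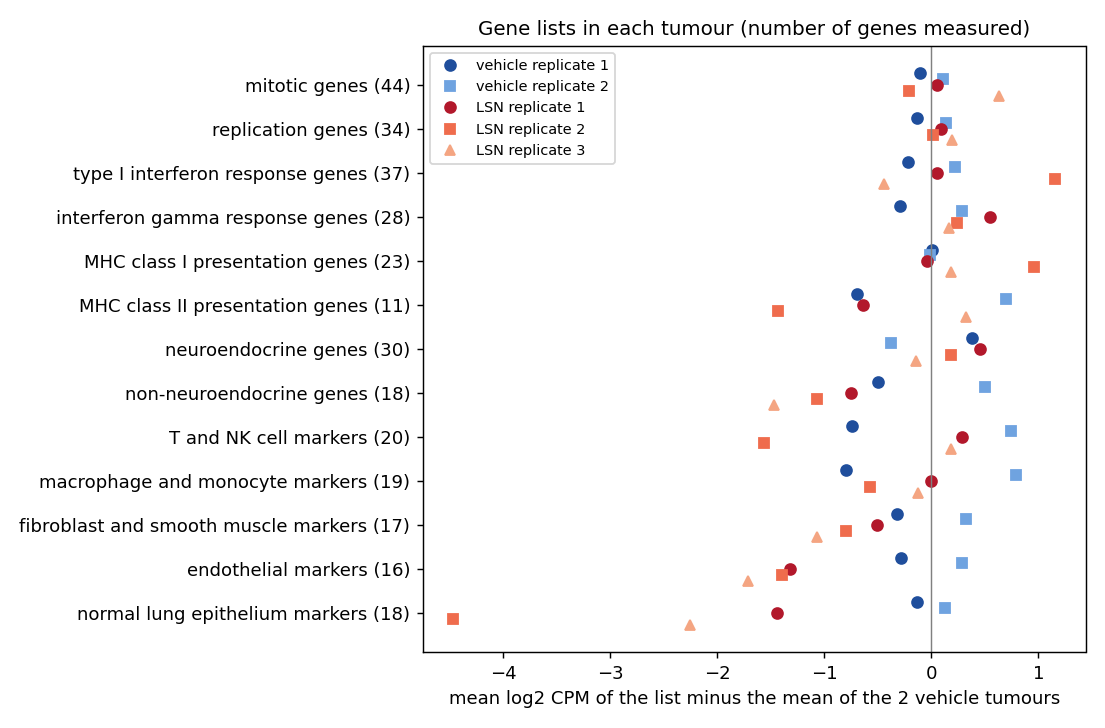
Mean log2 CPM of each list per tumour, minus the mean of the 2 vehicle tumours, with 1 point per tumour and the number of measured genes in brackets. Type I interferon and MHC class I genes were highest in LSN replicate 2, at 5.27 and 7.28 log2 CPM, and the means of normal lung epithelium and endothelial markers were lower in all 3 LSN tumours.

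Immune cell markers were not highest in LSN replicate 2, the tumour with the highest type I interferon and MHC class I lists. T and NK cell markers had means of -0.16 and 1.33 log2 CPM with vehicle and 0.87, -0.98 and 0.77 with LSN replicates 1, 2 and 3, so that LSN replicate 2 was lowest. Their median log2 fold change was -0.43 (limma camera, adjusted p = 0.392). Macrophage and monocyte markers had a median of 0.18 and a mean of -0.23 (adjusted p = 0.92 by limma camera), and Ccr2, a monocyte chemokine receptor, was lower in all 3 LSN tumours, at 2.49 against 10.9 CPM (DESeq2, adjusted p = 0.0279). The 19 members were split, with 9 above 0 and 10 below. C1qa, C1qb and C1qc were at 0.50, 0.62 and 0.67, and Marco and Chil3 at -2.77 and -2.08, with groups that overlapped. These 5 genes were chosen after their values were seen. MHC class II genes were below 0 for all 11 members, with a median of -0.47 (limma camera, adjusted p = 0.0989). Checkpoint genes other than Cd274 varied in direction, and the 14 members had a median of 0.07 and a mean of -0.16 (limma camera, adjusted p = 0.893). Nucleic acid sensing genes had a median of 0.10 over 22 members (limma camera, adjusted p = 0.171), 0.30 without vehicle replicate 2 and 0.27 without LSN replicate 3, both called, with Tmem173, the gene of STING, at 33.4 against 29.9 CPM and Mb21d1, the gene of cGAS, at 60.1 against 40.0 CPM. Adar, an RNA-editing enzyme, was higher in all 3 LSN tumours, at 81.3 against 55.3 CPM. Single tumours decided these medians. Without vehicle replicate 1, limma camera called T and NK cell markers lower (-1.11), MHC class II genes lower (-1.16) and macrophage markers lower (-0.67), whereas without vehicle replicate 2 it called macrophage markers higher (1.03), and without LSN replicate 3 MHC class II genes lower (-0.84). Medians on the other side of 0, not called, were 0.235 and 0.018 for MHC class II and 0.29 and 0.39 for T and NK cells without vehicle replicate 2 and LSN replicate 2. Checkpoint genes were at -0.72 without vehicle replicate 1, 0.62 without vehicle replicate 2, and -0.15 and -0.06 without LSN replicates 1 and 2, and nucleic acid sensing genes at -0.058 and -0.08 without vehicle replicate 1 and LSN replicate 2, none called. With the immune and stromal covariate, MHC class II genes (0.59), T and NK cell markers (0.74) and macrophage markers (0.99) were called higher. The T and NK cell and macrophage markers are part of that covariate, so their calls with it test nothing.

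Other immune markers were lower on average in the LSN group. Neutrophil markers had a median of -1.23 (limma camera, adjusted p = 0.00323), dendritic cell markers one of -0.94 (adjusted p = 0.0106) and B and plasma cell markers one of -1.12 (adjusted p = 0.03). With an estimated correlation these became adjusted p = 0.622, adjusted p = 0.49 and adjusted p = 0.649. Hdc, the histamine-forming enzyme of neutrophils and mast cells, was at 2.72 against 23.8 CPM and was the 1 neutrophil marker that passed in edgeR adjusted over the list alone. The dendritic cell receptors Flt3, at 0.751 against 2.11 CPM, and Clec9a, at 1.08 against 2.61 CPM, were lower in all 3 LSN tumours. Pou2af1, a coactivator of B cells, reached 232 CPM in LSN replicate 1 and 5.70 to 20.8 CPM in the other tumours. The B and plasma cell list as a whole had its lowest mean in LSN replicate 1, at 1.98 log2 CPM against 2.87 to 4.87 elsewhere. NF-kB and inflammatory cytokine genes had a median of -0.25 (limma camera, adjusted p = 0.0133; adjusted p = 0.622 with an estimated correlation), with Icam1, an adhesion molecule, at 23.1 against 73.2 CPM. Without vehicle replicate 2 the medians of the neutrophil, dendritic cell, B and plasma cell and NF-kB lists were 0.14, -0.30, -0.058 and 0.30, and limma camera called none of these 4 lists then or without LSN replicate 2. Without LSN replicate 1, the B and plasma cell median was -0.28 and the NF-kB median -0.39, neither called. Without vehicle replicate 1, the neutrophil, B and plasma cell and NF-kB medians were -2.55, -2.11 and -1.01, and without LSN replicate 3 the B and plasma cell median was -1.73, all called. With either covariate none of the 4 lists was called.

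Neurod1 (chromosome 2, 79452521 to 79456751), a neuroendocrine transcription factor, had 693 and 199 counts in the vehicle tumours and 14, 8 and 0 in the LSN tumours. Its log2 fold change was -5.90 ± 1.41 (SE), with an adjusted p of 0.9996 by edgeR and 0.000652 by DESeq2. The 30 neuroendocrine genes together had a median of 0.36 (limma camera, adjusted p = 0.0598), and Syt1, a synaptic vesicle protein, was at 604 against 226 CPM. The list was called higher without vehicle replicate 1 (0.80), without LSN replicate 3 (0.42) and with total counts (0.27; limma camera, adjusted p = 0.0338) or no count filter (0.36), and its median was 0.085 without vehicle replicate 2. Mycl was at 96.8 against 58.7 CPM and Mycn at 24.1 against 27.7 CPM, with overlapping groups. Of the tumour suppressors lost in many small cell lung cancers, Rb1 had 70.6 against 81.0 CPM and Rbl2 39.3 against 30.8 CPM, while Trp53 transcripts were lower in all 3 LSN tumours, at 25.1 ± 2.91 CPM (SD, n = 3) against 41.5 ± 3.48 CPM (SD, n = 2). Deleted exons were not examined here.

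**Figure D2:**
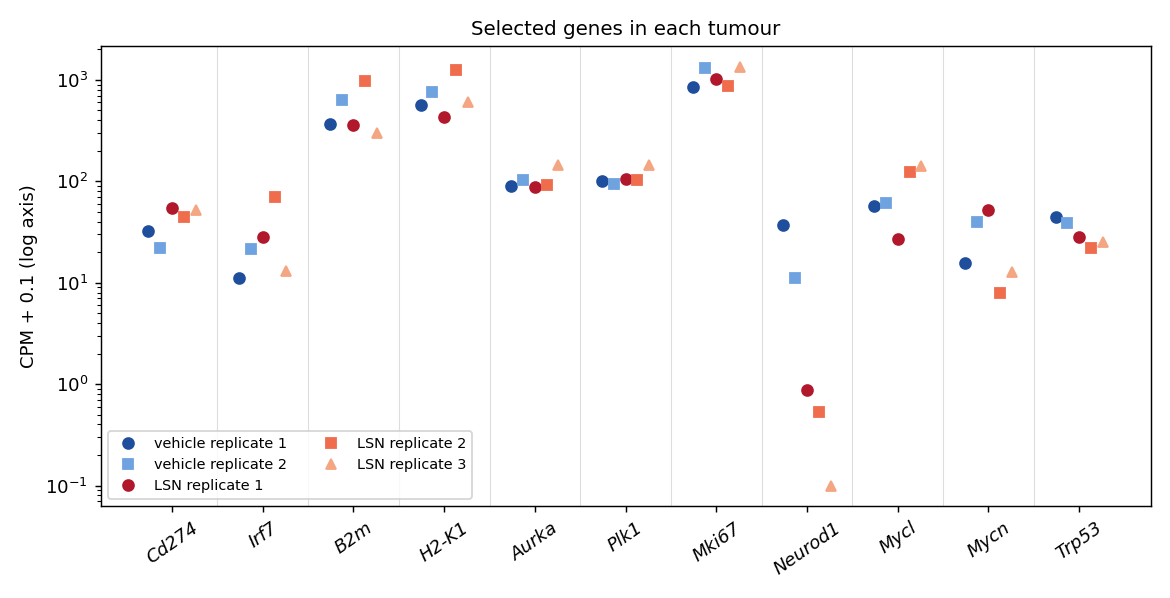
CPM plus 0.1 on a log axis for 11 genes, with 1 point per tumour. Cd274 lies between 44.0 and 54.1 CPM in the LSN tumours and at 32.2 and 22.1 CPM in the vehicle tumours, and Neurod1, with 0 counts in LSN replicate 3, is lower in every LSN tumour.

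Non-neuroendocrine genes were lower with LSN for all 18 measured members of 21, with a median of -1.14 (limma camera, adjusted p = 5.67e-09; adjusted p = 0.49 with an estimated correlation) and of -0.64 without vehicle replicate 2 (adjusted p = 0.0127). Cav1, a caveolar protein, was at 23.2 against 89.0 CPM, and Cyr61, a target of YAP, at 8.68 against 33.1 CPM, and 12 of the 18 genes were lower in every LSN tumour, where chance gives 10%. In edgeR, 0 members passed over all genes and 0 adjusted over the list alone, with 7 at an unadjusted p under 0.05. These genes are also expressed in stromal and endothelial cells, and the list moved with the markers of those cells. Fibroblast and smooth muscle markers had a median of -0.76 (limma camera, adjusted p = 5.91e-06; adjusted p = 0.49 with an estimated correlation), with Dpt, a matrix protein, at 8.37 against 21.2 CPM and Col6a1, a collagen, at 39.0 against 79.7 CPM. The fibroblast median was -1.26 without vehicle replicate 1 and -0.46 without vehicle replicate 2, both called.

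Normal lung epithelium markers were lower in the LSN group as a whole. All 18 were below 0, with a median of -2.46 (limma camera, adjusted p = 5.57e-12; adjusted p = 0.49 with an estimated correlation), and 15 were lower in every LSN tumour, where chance gives 10%. Sftpc, surfactant protein C of alveolar type 2 cells, was at 521 ± 301 CPM (SD, n = 3) against 2707 ± 1668 CPM (SD, n = 2), and Scgb1a1, the club cell secretoglobin, at 218 ± 213 CPM (SD, n = 3) against 3000 ± 972 CPM (SD, n = 2). These 2 genes were chosen after their values were seen, as the most abundant of the list. Lamp3, of alveolar type 2 cells, was at 20.4 against 108 CPM and Hopx, of alveolar type 1 cells, at 10.3 against 40.3 CPM. Endothelial markers had a median of -1.57 over 16 genes (limma camera, adjusted p = 1.38e-12; adjusted p = 0.49 with an estimated correlation), with Cldn5, a tight junction protein, at 4.32 against 29.2 CPM (DESeq2, adjusted p = 0.000647) and Cdh5, VE-cadherin, at 19.9 against 82.1 CPM. By edgeR, 0 members of these 2 lists passed over all genes, 10 of each reached an unadjusted p under 0.05, and 9 of each passed adjusted over the list alone.

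The genes with the smallest p-values among those lower with LSN were led by Adgrf5 (chromosome 17, 43360451 to 43459557), a receptor of lung endothelium and alveolar cells, with a log2 fold change of -2.22 ± 0.31 (SE), from 106 to 22.8 CPM. Drc7, of the motile cilium, was at 0.720 against 8.09 CPM, Sdc4, a cell surface proteoglycan, at 17.5 against 61.7 CPM, S100a6, a calcium-binding protein, at 13.8 against 58.3 CPM and Cavin1, of caveolae, at 29.6 against 105.0 CPM. None passed in edgeR (adjusted p = 0.9996), and all 5 passed in DESeq2, with adjusted p between 9.32e-07 and 0.0118. Genes with cilium and dynein symbols (Dnah, Cfap, Drc, Rsph, Dnai and Dnaaf families), a set chosen after the values were seen, were lower for 49 of 59 members. Their median edgeR log2 fold change was -1.86. In edgeR, 26 of them were lower at an unadjusted p under 0.05, and 9 were among the 86 genes lower in DESeq2.

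Further lists marked tissue handling and other tissues. Red blood cell markers had a median of -2.76 (limma camera, adjusted p = 0.012; adjusted p = 0.622 with an estimated correlation), with Hba-a1 at 64.2 against 264 CPM. Mesothelial markers had a median of -0.68 (limma camera, adjusted p = 0.00379; adjusted p = 0.49 with an estimated correlation), with Upk3b, of the pleural lining, at 8.30 against 17.1 CPM. Immediate early and stress genes were below 0 for 17 of 20 members, with a median of -0.59 (limma camera, adjusted p = 0.00124; adjusted p = 0.49 with an estimated correlation), and Ier2 and Ier3 were lower in all 3 LSN tumours, at 22.1 against 46.2 CPM and 5.18 against 15.9 CPM. The lists of p53 targets (-0.08, adjusted p = 0.362), hypoxia and glycolysis (0.05, adjusted p = 0.725), senescence (-0.54, adjusted p = 0.14), muscle (-1.04, adjusted p = 0.453), liver (-1.12, adjusted p = 0.149) and thymus with lymph node markers (-0.71, adjusted p = 0.402) were not called by limma camera. With a tumour left out it called hypoxia and glycolysis higher (0.38, without LSN replicate 1), senescence lower (-0.75, without vehicle replicate 1), and muscle (-1.75) and thymus with lymph node markers (-1.19) lower without LSN replicate 3. Hypoxia and glycolysis had medians of -0.35 and -0.28 without vehicle replicate 2 and LSN replicate 2, and was called lower with the normal lung covariate (-1.26), as was senescence (-0.69). Liver markers were called lower with the filter of 1 CPM in 2 samples (-2.10). Without LSN replicate 2, medians were -0.31 for senescence, -0.17 for liver and -0.1 for thymus with lymph node markers, none called. The median of p53 targets was -0.009 without vehicle replicate 1 and -0.321 without vehicle replicate 2. Red blood cell and mesothelial markers were not called without vehicle replicate 1 (limma camera, adjusted p = 0.0787 and 0.0585). Medians that stayed called were -1.14 for red blood cells without LSN replicate 2, -1.04 for mesothelium without LSN replicate 1, and -0.31 for immediate early genes without vehicle replicate 2, or -0.30 with the immune and stromal covariate. With the normal lung covariate red blood cell markers were called higher (1.90). The mean log2 fold changes were -0.03 for hypoxia and glycolysis and -0.09 for muscle. Myh4, a skeletal muscle myosin, had 0 counts in both vehicle tumours and LSN replicate 2, and 13.5 and 7.52 CPM in LSN replicates 1 and 3. Across the 29 lists, limma camera called 15, of which 0 were called with an estimated correlation, the smallest adjusted p being 0.49, and 0 by fry, with a smallest adjusted p of 0.112. Without LSN replicate 2, camera called 9 lists. No member of any list passed in edgeR over all genes, and adjusted over the list alone members passed only in the normal lung, endothelial and neutrophil lists.

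Genes higher with LSN at the smallest p-values were led by Wfikkn2 (chromosome 11, 94235956 to 94246005), a secreted protease inhibitor that binds growth factors of the TGF-beta family. It was at 12.01 ± 0.648 CPM (SD, n = 3) against 1.05 ± 0.337 CPM (SD, n = 2), a log2 fold change of 3.51 ± 0.55 (SE), with an adjusted p of 0.9996 by edgeR and 7.92e-10 by DESeq2. Tmem132d, a membrane protein, was at 22.5 against 3.63 CPM (DESeq2, adjusted p = 4.76e-05), and Rgs9, a regulator of G protein signalling, at 164 against 53.8 CPM (DESeq2, adjusted p = 0.00991). Tex2, at 115 against 47.8 CPM, and Rnf213, a ubiquitin ligase, at 116 against 48.8 CPM, were not called by DESeq2 (adjusted p = 0.0505 and 0.11). Of these 5 genes, 4 lie on chromosome 11. Of the 14 genes higher in DESeq2, 5 had 0 counts in both vehicle tumours and counts in only 1 LSN tumour each. These were Serpina3j in LSN replicate 3, and Krt12, Prph2, Fam240b and Cntnap3 in LSN replicate 1.

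Of the 190 genes higher at an unadjusted p under 0.05, 101 (53.2%) lay on chromosome 11, which holds 7.9% of the tested genes, an odds ratio of 14.1 (Fisher's exact test across genes, which are not independent, p = 1.87e-60). The median deviation of chromosome 11 genes from their mean over all tumours was -0.23 on the log2 scale in both vehicle tumours and 0.21, -0.02 and 0.28 in LSN replicates 1, 2 and 3. Other chromosomes deviated in single tumours. Chromosome 12 was at -0.67 in LSN replicate 2 and 0.62 in LSN replicate 3, and chromosome 14 at -0.40 in vehicle replicate 1.

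**Figure D3:**
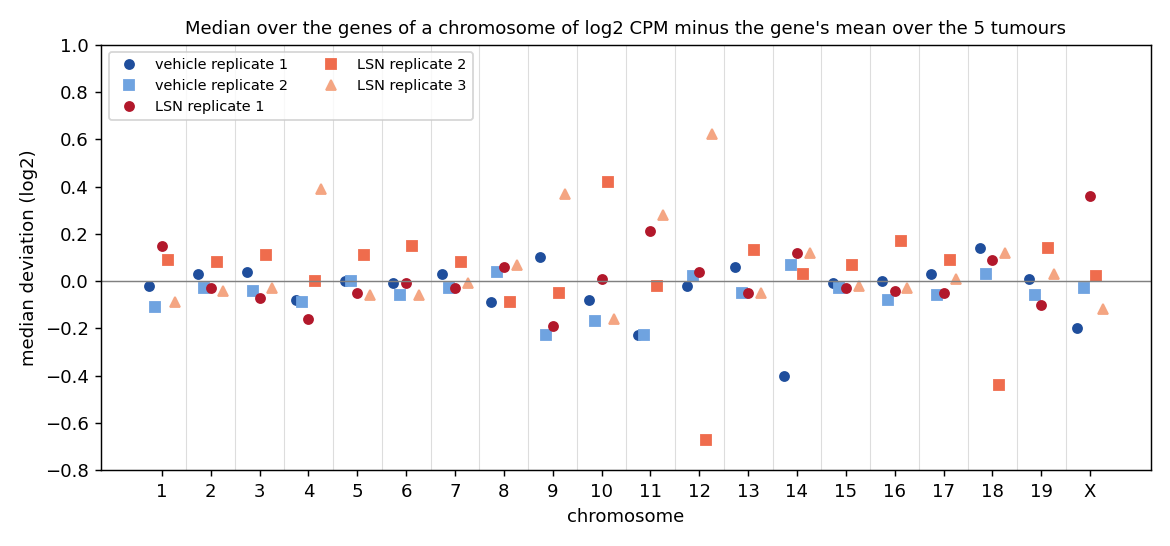
Median over the genes of each chromosome of log2 CPM minus the gene's mean over the 5 tumours, with 1 point per tumour. On chromosome 11 both vehicle tumours lie at -0.23 and the LSN tumours at -0.02 to 0.28, and chromosome 12 spans -0.67 to 0.62 within the LSN group.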

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

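DESeq2 with single tumours left out, the normal lung covariate and the removal of chromosome 11 were chosen only after the results were seen. No paired analysis was possible because the labels give every tumour its own number. DESeq2 called 100 genes, 14 higher and 86 lower, where edgeR and limma-voom called 0, and edgeR called 0 under its other scalings, filters, covariates and with each tumour left out. At an unadjusted p under 0.05, the 190 genes higher became 291 with DESeq2, 116 with total counts, 562 with the normal lung covariate and 89 without chromosome 11, and 98 to 237 with a tumour left out. The 574 genes lower became 927 with DESeq2, 370 with the immune and stromal covariate and 344 with the normal lung covariate, and 309 to 963 with a tumour left out. Leaving out a tumour moved the DESeq2 count to between 36 and 483. Of 1300 values of the 88 named genes under alternatives, 69 changed sign, in 30 genes, and none of these was called; 12 named genes passed in DESeq2 and 0 in the edgeR and limma-voom alternatives.

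The 15 lists called became 0 with an estimated correlation and 0 with fry, and 9 to 19 with a tumour left out. Under both of those tests the medians were by construction those of camera and none was called: 0.17 for mitotic genes, 0.27 for type I interferon, 0.38 for interferon gamma, 0.37 for MHC class I, -1.14 for non-neuroendocrine genes, -2.46 for normal lung, -1.57 for endothelium and -0.76 for fibroblasts. Leave-one-out medians ran from -0.082 to 0.30 for mitotic genes, -0.11 to 0.68 for type I interferon, 0.16 to 0.62 for interferon gamma, 0.09 to 0.54 for MHC class I, -1.01 to 0.30 for NF-kB genes, -2.11 to -0.058 for B and plasma cell markers and -0.67 to 1.03 for macrophage markers. With the immune and stromal covariate, type I interferon (0.10) and MHC class I (0.069) were no longer called, MHC class II (0.59) and T and NK cells (0.74) were called higher, against their main direction, and NF-kB genes (0.089) and B and plasma cells (-0.13, by its test) turned without a call. With the normal lung covariate, interferon gamma (0.29) and normal lung markers themselves (-0.35) were no longer called, and type I interferon (-0.72), MHC class I (-0.67), hypoxia and glycolysis (-1.26), T and NK cells (1.503) and red blood cells (1.90) were called in the opposite direction. Neutrophils (-0.23, by its test) and dendritic cells (0.21) turned without a call. Both covariates leave 2 residual degrees of freedom, and the normal lung covariate was lower in every LSN tumour. T and NK cell and B and plasma cell markers are part of the immune and stromal covariate. Normal lung markers make up the other covariate. The changes of these lists with the covariate that holds them test nothing, and the cause of the other turns was not tested. Scaling and filters changed none of the calls of the 8 lists given above for both tests. At this spread edgeR recovered 0% of 2-fold changes simulated with independent genes, so that differences of that size may have been missed by it here.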

Other observations

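The tests of library depth, scaling, immune cells in LSN replicate 2, LSN replicate 2 alone and chromosome dosage were chosen only after the result was seen.

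Some genes differed between tumours across the treatment. Pou3f2 was at 44.6 and 59.3 CPM in vehicle replicate 2 and LSN replicate 1 and at 0.968 CPM in vehicle replicate 1, 0.0536 CPM in LSN replicate 2 and 0.265 CPM in LSN replicate 3. Nr2f1 was at 198 and 60.6 CPM there, and at 5.59, 0.107 and 0.0529 CPM in the same 3 others. Esrp1, an epithelial splicing regulator, showed the opposite, at 8.71 and 3.04 CPM in the first pair and 173, 252 and 423 CPM in the others. Tph1, the enzyme that starts serotonin synthesis, was at 741 CPM in vehicle replicate 1 and 6405 CPM in LSN replicate 2, and at 0.670, 3.15 and 2.49 CPM in vehicle replicate 2 and LSN replicates 1 and 3. Mycn was at 39.8 and 51.9 CPM in vehicle replicate 2 and LSN replicate 1 and at 15.7, 7.77 and 12.6 CPM in the others. These genes other than Mycn were chosen after their values were seen, from the first principal component.

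Sex-linked transcripts differed between the tumours as well. Xist had 26167 counts in vehicle replicate 2, 709 in LSN replicate 2 and 3 to 44 in the other tumours, and Ddx3y, on the Y chromosome, had 1291, 1083 and 2314 counts in vehicle replicate 1 and LSN replicates 1 and 3 and 1 and 2 counts in vehicle replicate 2 and LSN replicate 2. Clca1, a secreted protein of mucous cells, was also chosen after its values were seen. Among the genes called by DESeq2 it had the lowest log2 fold change, at -8.94. It had 6925 and 161 counts in the vehicle tumours and 19, 1 and 1 in the LSN tumours.

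All 10 splits of the 5 tumours into 2 and 3 were fitted. For genes at an unadjusted p under 0.05 the real split gave 764 and 4 of the 10 splits gave as many, the highest other being 2561. For DESeq2 calls the real split gave 100 and 6 of the 10 gave as many, the highest other being 1355. Both of the highest counts came from setting vehicle replicate 2 and LSN replicate 1 against the rest, which points to a structure of the samples other than treatment, and edgeR called 2 genes in that split. For called lists the real split gave 15, 2 of the 10 gave as many and the highest other was 19. With 10 splits no share under 0.05 can be reached.

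Lower normal lung and endothelial markers in the LSN tumours may reflect less adjacent lung in the pieces sequenced. Macrophages of the alveoli would then be fewer too. Of their 6 markers, 5 were measured, Ear1, Siglecf, Krt79, Atp6v0d2 and Plet1, none of them in the fixed lists. Their median log2 fold change by edgeR was -2.07. The SE of their mean was 0.31, taken across these genes and not between tumours. The SE of single genes ran from 0.46 to 1.12. Counts ran from 22 to 1162 with vehicle and 3 to 485 with LSN. Atp6v0d2 (-0.65 ± 0.81, SE) had 150 and 1162 counts in vehicle replicates 1 and 2. It had 347, 468 and 485 in LSN replicates 1, 2 and 3. Whether tumour cells express these markers was not tested. Alveolar and airway members of the lung list had median edgeR log2 fold changes of -2.38 and -2.40 and, like the endothelial list, lower means in every LSN tumour. The tables argue against fewer reads, since the LSN libraries had 1.081 times the mean total count of the vehicle libraries; the list median of -2.45 or lower under 3 scalings tests nothing, as these moved all genes by 0.086 at most. A loss of lung and vessel cells with the inhibitor stays open and was not tested.

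Higher type I interferon and MHC class I lists with LSN could rest on 1 tumour. Without LSN replicate 2, their medians were -0.11 and 0.09 and neither was called, while interferon gamma genes were still called higher, at 0.31 (limma camera, adjusted p = 0.00804). With all tumours, the interferon gamma list was not called by limma camera with an estimated correlation (adjusted p = 0.565). Its median was 0.16 without vehicle replicate 1, and 0.27 and not called without LSN replicate 1. Immune cells as the source in LSN replicate 2 were argued against, since that tumour lay below the median of the 5 tumours in 5 of 5 immune marker lists. A response of the tumour cells to the inhibitor in that tumour, or a state it held before, remains open and was not tested.

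Higher chromosome 11 genes with LSN may come from chromosome dosage that differs between the tumours. After a fit of the edgeR log2 fold changes on GC content and gene length, the median of chromosome 11 was 0.32. The highest other autosome was then at 0.16, with an SD of 0.09 among the others. The fit lowered all autosomes about alike (chromosome 11 from 0.41, chromosome 10 from 0.24), so it did not remove the lead of chromosome 11. Chromosomes 7, 15 and 17 had median GC contents of 53.3, 52.9 and 53.7%, above the 52.5% of chromosome 11. Their medians before the fit, compared after the values were seen, were 0.04, 0.03 and 0.04. These values argue against GC content as the whole cause. The lead left after the fit argues against GC content and gene length, as fitted here, as the whole cause. Chromosome 11 genes with an unadjusted p of 0.05 or more had a median of 0.37, but they are 720 of its 818 genes with a mean log2 CPM above 4, so that this restates the pattern and tests nothing. In segments of 20 Mb along chromosome 11, the median log2 fold change ran from 0.37 to 0.46, so the shift was not confined to 1 region. These segments do not tell dosage from an effect of the inhibitor. DNA copy number was not analysed here. Chromosome dosage and an effect of the inhibitor on these genes both stay open.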
